A study of Arabidopsis thaliana with 36 samples.

How the data were processed

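RNA was measured in leaves of Arabidopsis thaliana, in wild type plants (accession Col-0) and in the pip5k1 pip5k2 double mutant, which carries mutations in 2 genes for phosphatidylinositol 4-phosphate 5-kinases. Leaves without inoculation (mock) or inoculated with conidia of the powdery mildew fungus Erysiphe cichoracearum were collected after 2, 5 and 7 d. There were 36 libraries in 12 groups of 3, which the series text calls biological replicates. Libraries were made with the Illumina TruSeq RNA kit, version 2, per the labels' protocols. That kit does not mark the strand, so reads of overlapping and antisense loci are not separated.

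The authors deposited 1 table with a value per locus and library. Per the submitters' processing notes the tools were STAR 2.4.0j, StringTie 1.0.3, HTSeq 0.6.0 and DESeq2 1.12.4 with genome build TAIR10; their settings are not given in the sources used here. From its values, the deposited table is a signal of read counts divided by 1 size factor per library: in each of the 36 libraries every value was a whole multiple of the smallest (100% of values within 0.001). Dividing by that step gave whole reads, 5715770 to 9443338 per library, and a single read was worth 0.72 to 1.42 units. In 2 libraries the step lay so near 1 that an automatic check of it gave no verdict, although their values were whole multiples like the rest. The table held 34910 loci, of which 33774 could be paired with a gene of the reference annotation by locus tag; 439 were named by a transcription start identifier and 264 were organelle loci. Some assembled loci merged neighbouring genes, which left 1999 rows beyond the first for a locus. Gene names were taken from the table and from the RefSeq annotation of TAIR10.1, and no coordinates are given because that build differs from the one in the notes.

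The comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. That plan expected raw counts and edgeR's quasi-likelihood test. Because the table held normalized values, the fallback written in the plan was used: limma 3.58.1 in R 4.3.3, with a trended prior, on log2(value + 1), with a mean for each of the 12 groups and all 36 libraries in 1 fit. Fold changes are therefore on the log2(value + 1) scale, which understates changes of loci with few reads. The filter was set after the table was seen: loci with a value of at least 10 in at least 3 libraries were tested, 18242 of 34910, and 16668 were not. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. There were 18 comparisons: inoculated against mock leaves in each line and day, the mutant against the wild type in mock and in inoculated leaves on each day and averaged over days, and the difference between the lines in the response to inoculation on each day and averaged. In each, values are inoculated minus mock or mutant minus wild type.

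The 25 gene lists held 372 members, of which 335 were tested. They covered the PIP5K family, other phosphoinositide metabolism, salicylic acid defence, jasmonate synthesis and response, ethylene and jasmonate defence, pattern recognition and early defence, camalexin and indole glucosinolates, aliphatic glucosinolates, penetration resistance and powdery mildew susceptibility, sugar transport and invertase, photosynthesis, senescence and chlorophyll breakdown, endoplasmic reticulum folding, abscisic acid and cold response, auxin response and transport, cell cycle, phenylpropanoids and anthocyanins, the circadian clock, qPCR reference genes, and markers of roots, flowers and pollen, the flowering transition, guard cells, phloem, and epidermis and cuticle. Lists were tested with camera on log2(value + 1) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 25 lists of a comparison, and again with a correlation estimated per list. The plan named log2 CPM for this test.

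Genes were named by this rule: PIP5K1 and PIP5K2 in every group; for each comparison the 4 raised and 4 lowered genes with the largest change among called genes with a symbol and at least 5 CPM in the higher group, in which every library of one group lay above every library of the other (not asked of averaged comparisons or differences in response); and up to 4 called members of each list. Errors on group means are SD over 3 libraries and errors on log2 changes are standard errors from limma. Where a group held 0 reads of a gene, the fold is a lower bound computed against 3 reads over the group; with 1 to 3 reads the ratio has an exact 95% interval. These cover counting error only, since reads without molecular identifiers are not independent molecules. Members with 0 reads in a group moved 3 of 29 list medians by at most 0.171, and those medians are given both ways.

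The limma test was checked on counts simulated for inoculated and mock wild type leaves at 2 d. Genes varied independently at 1 dispersion of 0.01, against a common 0.00742 estimated from the recovered reads. Among 17330 loci limma recovered 62.7% of 67 changed 1.5-fold and 100% of 67 changed 2-fold, with 10 false calls and 0 where nothing changed. camera found 20 of 20 shifted lists of such genes, with 1 false call among 180. Replicate libraries differed by more than sampling noise in each of the 36 pairs, with mean chi-square values of 1.49 to 15.2, so none was counted as a repeat of another.

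The alternatives were edgeR 4.0.16 with median-of-ratios factors and DESeq2 1.42.0 on the recovered reads, no filter, a pseudocount of 0.1, only the libraries of the groups compared, the replicate number as a block, a minimum absolute log2 change of 1, and leaving out each library in turn. edgeR with TMM factors was added after the data were seen. Reads from near-identical copies are uncertain, in particular for PDF1.2A, PDF1.2B, PDF1.2C and PDF1.3, the RBCS and LHCB families, ATCSLA15 and CSLA01, and the HR genes.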

Results

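The series measured leaf RNA in wild type plants and in the pip5k1 pip5k2 mutant, each without inoculation (mock) or inoculated with the powdery mildew Erysiphe cichoracearum, at 2, 5 and 7 d. Each of the 12 combinations of line, treatment and day had 3 libraries, 36 in all. Values are normalized read counts per library, given as mean ± SD with n = 3, and changes are log2 differences ± standard error from limma. The 100 most abundant loci took 29.7% of reads in wild type mock leaves at 2 d, 27.8% at 5 d and 29.7% at 7 d, against 22.2%, 17.7% and 20.6% in inoculated wild type leaves. In the mutant the shares were 32.2%, 30.2% and 28.4% in mock and 28.3%, 25% and 23.1% in inoculated leaves. Organelle loci took 0.627% of reads in replicate 3 of the mock mutant leaves at 5 d, which also had the lowest depth, and at most 0.26% in the other mock libraries.

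PIP5K1 and PIP5K2 encode kinases that make phosphatidylinositol 4,5-bisphosphate, a membrane lipid that takes part in vesicle traffic and signalling. Transcripts of both genes were lower in the mutant in every comparison of the lines and were still detected there. PIP5K1 (AT1G21980) measured 377.5 ± 41.3, 268 ± 25.1 and 280 ± 14.1 in wild type mock leaves at 2, 5 and 7 d, and 41.56 ± 9.69, 48.91 ± 10 and 57.34 ± 22.7 in mutant mock leaves. PIP5K2 (AT1G77740) measured 534.7 ± 34, 450.1 ± 8.25 and 649.3 ± 32 in wild type mock leaves and 189.7 ± 35.7, 155.9 ± 33.4 and 114.7 ± 4.09 in mutant mock leaves. In inoculated leaves PIP5K1 measured 207.9 ± 19.4, 121.8 ± 12.1 and 118.6 ± 19.1 in the wild type and 33.31 ± 10.3, 38.1 ± 6.33 and 40.29 ± 11.1 in the mutant. PIP5K2 measured 567 ± 47.8, 478.8 ± 54.5 and 438.7 ± 74.4 in inoculated wild type and 145.6 ± 10, 158.4 ± 11.3 and 157.4 ± 6.78 in inoculated mutant leaves. The line difference at 2 d in mock leaves was -3.17 ± 0.23 for PIP5K1 (limma, Benjamini-Hochberg adjusted p = 2.36e-14) and -1.50 ± 0.12 for PIP5K2 (limma, Benjamini-Hochberg adjusted p = 6.57e-13). Infection lowered PIP5K1 in the wild type, by -0.86 at 2 d, -1.13 at 5 d and -1.24 at 7 d (limma, Benjamini-Hochberg adjusted p = 0.00217, 5.39e-05 and 1.33e-05).

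**Figure D1:**
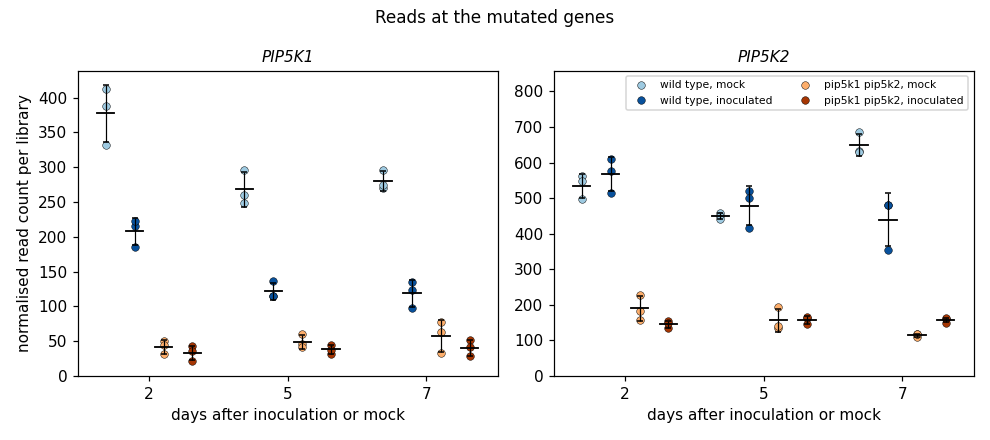
Normalized read counts of PIP5K1 and PIP5K2 in each library, by line, treatment and day, with the mean of each group of 3. Every mutant library lies below every wild type library of the same treatment and day.

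Counts of list members given for each gene list below are over all tested loci; where adjusting over the list alone changed a count, that count follows in the words adjusted over the list alone. List tests are from camera, and their p values are Benjamini-Hochberg adjusted over the 25 lists of a comparison. Where a call was lost when the correlation between genes was estimated, that second adjusted p follows. For each gene named as most raised or most lowered on a single day, other than for differences in response, all 3 libraries of one group lay above all 3 of the other, as the naming rule requires; chance alone gives this for 10% of genes.

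**Figure D2:**
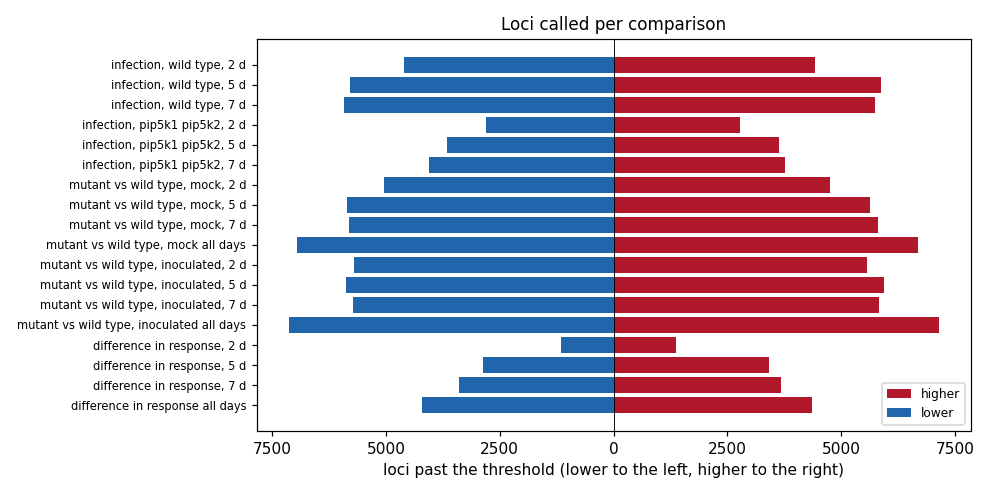
Loci called higher and lower in each of the 18 comparisons (limma, Benjamini-Hochberg adjusted p under 0.05).

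The first comparison asked how wild type leaves respond to powdery mildew. By 2 d salicylic acid defence, camalexin synthesis and the folding machinery of the endoplasmic reticulum had risen and cuticle and auxin genes had fallen. Senescence genes rose on all 3 days, and at 5 and 7 d jasmonate genes, some of which had risen at 2 d, had fallen. Phenylpropanoid genes were called lower at 2 and 7 d, and the defensin genes PDF1.2A and PDF1.2C fell at 7 d. In limma 9030 loci were called at 2 d, 4419 higher and 4611 lower, 11668 at 5 d, 5875 higher and 5793 lower, and 11657 at 7 d, 5729 higher and 5928 lower.

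At 2 d the most raised genes were FMO1 (AT1G19250), which makes the immune signal N-hydroxypipecolic acid, the germin-like protein gene GLP9 (AT4G14630), the methyltransferase gene PXMT1 (AT1G66700) and the glutathione transferase gene GSTU10 (AT1G74590). FMO1 rose from 2.136 ± 1.06 to 193.9 ± 15.9, GLP9 from 1.752 ± 2.19 to 96.54 ± 16.3, PXMT1 from 3.201 ± 0.0933 to 161.9 ± 17.7 and GSTU10 from 4.981 ± 2.65 to 196 ± 6.21. Most lowered were the thionin gene THI2.2 (AT5G36910) (-3.77 ± 0.31), the epidermal gene PDF1 (-3.75 ± 0.54), bHLH39 (AT3G56980), a regulator of iron uptake (-3.46 ± 0.46), and XTH9 (AT4G03210), which encodes a cell wall enzyme (-3.31 ± 0.28). At 5 d the senescence protease gene SAG12 (AT5G45890) had 0 reads in the 3 mock libraries and 3099 ± 155 in inoculated leaves, at least 2880-fold higher. The other most raised genes at 5 d were the fatty acid dioxygenase gene DOX1 (AT3G01420), the protease inhibitor gene KTI1 (AT1G73260), which rose from 1.457 ± 1.27 to 1552 ± 253, and the sugar starvation gene DIN2 (AT3G60140), which was at least 353-fold higher. DOX1 rose from 0.387 ± 0.67 to 1455 ± 33.1, a ratio of 4040 (95% interval 725 to 160000). Most lowered at 5 d were DDF1 (AT1G12610) and RRTF1 (AT4G34410), transcription factors of stress responses, the germin-like gene GER3 (AT5G20630) and the transcription factor gene BZIP34 (AT2G42380). RRTF1 fell from 676.8 ± 75.2 to 8.792 ± 3.33 and BZIP34 from 136.5 ± 9.99 to 1.408 ± 1.23, while DDF1 and GER3 had 0 reads in inoculated leaves and were at least 96.7-fold and 75.8-fold lower. At 7 d KTI1 (9.09 ± 0.41), DOX1, SAG12 and the methyltransferase gene CCOAMT (AT1G67980) were most raised, SAG12 at least 299-fold. Most lowered at 7 d were the defensin genes PDF1.2C and PDF1.2A, the hydrolase gene NUDT24 (AT5G19470), at least 234-fold lower, and CSLA01 (AT4G16590), which encodes a mannan synthase (-6.01 ± 0.15). PDF1.2A (AT5G44420) fell from 5829 ± 513 to 27.65 ± 1.25 and PDF1.2C (AT5G44430) from 3227 ± 111 to 4.508 ± 0.931. Fitted log2 values of genes with 0 reads depend on the pseudocount and are no bound.

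All 24 tested genes of salicylic acid defence rose on each day, with medians of 2.66, 3.36 and 3.66 (camera adjusted p = 1.88e-26, 1.73e-20 and 2.64e-21). PR1 (AT2G14610), the marker of this pathway, rose from 1008 ± 68.6 to 8078 ± 357 at 2 d, from 131.9 ± 33.5 to 15810 ± 1410 at 5 d and from 250.5 ± 30.2 to 15470 ± 2720 at 7 d. ICS1 (AT1G74710), which makes salicylic acid, rose from 211.8 ± 9.99 to 1849 ± 87.7 at 2 d, and ALD1 (AT2G13810), which acts with FMO1, rose from 5.46 ± 2.09 to 428.5 ± 25.4 at 5 d. Of 16 genes for pattern recognition and early defence 12, 11 and 15 rose and 1, 3 and 1 fell, with medians of 1.19, 0.90 and 2.38 (camera adjusted p = 8.02e-08, 0.00131 and 1.09e-08). They include the receptor kinase gene FRK1, raised by 3.88, 5.74 and 6.80, and NHL10, raised by 4.93, 6.10 and 7.18. Of 14 camalexin and indole glucosinolate genes 9, 11 and 11 rose and 1, 2 and 2 fell, with medians of 1.43, 1.14 and 1.37 (camera adjusted p = 2.63e-07, 1.9e-05 and 0.000133). With members at 0 reads set to their bound the median at 2 d was 1.32. PAD3 (AT3G26830), which makes camalexin, rose from 10.34 ± 1.89 to 285.7 ± 22.6 at 2 d and from 25.63 ± 5.54 to 1084 ± 67.9 at 5 d, and CYP71A13 of the same pathway rose by 4.22, 5.52 and 5.23. Of 17 genes of penetration resistance and mildew susceptibility 11 rose at 2 d (12 adjusted over the list alone), 12 at 5 d and 14 at 7 d, and 2 fell on each day. Medians were 0.90, 0.67 and 1.51 (camera adjusted p = 8.84e-06, 0.00122 and 3.7e-06), and the median at 5 d was also 0.67 with members at their bound. MLO12 and MLO6, related to a gene that mildew fungi need for entry, rose by 2.69 and 2.11 at 2 d and by 4.72 and 3.70 at 7 d.

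All 17 tested genes of endoplasmic reticulum folding rose on each day, with medians of 2.17, 1.96 and 1.43 (camera adjusted p = 1.9e-24, 4.57e-15 and 9.5e-12). Among them the chaperone gene BIP3 (AT1G09080) rose from 39.51 ± 3.17 to 569.1 ± 18 at 2 d, and PDIL2-2, which encodes a disulfide isomerase, by 3.05. Of 15 genes of senescence and chlorophyll breakdown 13, 14 and 14 rose and 1, 1 and 0 fell, with medians of 1.43, 1.66 and 1.62 (camera adjusted p = 7.78e-09, 1.23e-07 and 6.81e-10). SAG13 rose by 3.85, 5.79 and 5.20, and JUB1 by 4.43 and 5.48 at 2 and 5 d. Its role in senescence was not tested. Of 9 genes of sugar transport and invertase 3, 4 and 7 rose and 3, 3 and 1 fell, and the list was called only at 7 d, with a median of 1.07 (camera adjusted p = 0.116, 0.216 and 0.00132). At 5 d the median was -0.01 while the mean of 0.90 and the test were positive. The cell wall invertase gene CWINV1 (AT3G13790) rose from 86.15 ± 6.61 to 395.7 ± 35.6 at 2 d, from 40.26 ± 9.14 to 1042 ± 137 at 5 d and from 85.06 ± 6.77 to 1345 ± 159 at 7 d. The hexose transporter genes STP4 and STP13 rose by 1.92 and 1.90 at 2 d and by 3.01 and 2.43 at 7 d.

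Of 18 jasmonate genes 10 rose and 4 fell at 2 d, with a median of 0.48 (camera adjusted p = 0.0136, and 0.153 with an estimated correlation). At 5 d 0 rose and 17 fell, with a median of -0.94 (camera adjusted p = 4.89e-08), and at 7 d 2 rose (3 adjusted over the list alone) and 11 fell, with a median of -0.90 (camera adjusted p = 0.00032). VSP1 (AT5G24780), a storage protein gene induced by jasmonate, fell from 3075 ± 64.9 to 67.95 ± 20.2 at 5 d, and VSP2 fell by -4.47 at 5 d and -4.65 at 7 d. Of 8 genes of ethylene and jasmonate defence 4, 4 and 1 rose and 2, 4 and 5 fell, with medians of 0.45, -0.10 and -3.55 (camera adjusted p = 0.448, 0.874 and 0.00948, the last 0.162 with an estimated correlation). At 5 d the test was upward while the median and the mean of -0.20 were negative. All 39 tested photosynthesis genes fell on each day, with medians of -0.87, -1.23 and -0.95 (camera adjusted p = 6.5e-21, 4.6e-19 and 3.87e-14, and 0.122, 0.127 and 0.174 with an estimated correlation). RBCS2B, for the small subunit of Rubisco, fell by -1.92, -2.89 and -2.39. Of 11 epidermis and cuticle markers 10, 11 and 11 fell and 0 rose, with medians of -1.24, -2.06 and -2.64 (camera adjusted p = 8.95e-09, 5.6e-08 and 1.09e-08). CER1 (AT1G02205), which makes wax alkanes, fell from 2798 ± 168 to 389.1 ± 12.6 at 2 d and from 1674 ± 73.9 to 63.41 ± 10.4 at 5 d, and the lipid transfer gene LTP1 (AT2G38540) fell from 1904 ± 107 to 168.9 ± 15.7 at 5 d.

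Of 16 phenylpropanoid and anthocyanin genes 0, 4 and 3 rose and 10, 11 and 12 fell, with medians of -0.75, -0.73 and -2.40 (camera adjusted p = 0.000179, 0.086 and 7.74e-05). At 7 d chalcone synthase CHS, which opens the flavonoid pathway, fell by -4.60 and LDOX of the anthocyanin branch by -4.63. Of 18 auxin genes 14, 13 and 13 fell (15, 14 and 13 adjusted over the list alone) and 0, 3 and 3 rose (0, 3 and 4 adjusted over the list alone). Medians were -0.82, -1.51 and -1.47 (camera adjusted p = 1.87e-05, 0.000216 and 0.00307), with IAA29, a repressor of auxin response, lowered by -1.47, -2.59 and -3.88. Of 11 cell cycle genes 8, 7 and 11 fell (9, 8 and 11 adjusted over the list alone) and 0 rose. Their medians were -1.60, -2.74 and -1.92 (camera adjusted p = 0.0137, 0.0217 and 0.00307, the first 2 values 0.0739 and 0.0832 with an estimated correlation). Of 13 aliphatic glucosinolate genes 9, 10 and 10 fell (10, 10 and 10 adjusted over the list alone) and 0, 1 and 1 rose. Medians were -0.42, -0.81 and -0.54 (camera adjusted p = 0.00156, 0.000216 and 0.00307), with the regulator MYB29 lowered by -0.71, -2.03 and -2.03. Of 21 genes of abscisic acid and cold response 9, 2 and 6 rose (9, 3 and 6 adjusted over the list alone) and 7, 17 and 11 fell. The list was called only at 5 d, with medians of 0.17, -1.11 and -0.39 (camera adjusted p = 0.448, 3.11e-05 and 0.2). Of 5 phloem markers 5, 5 and 4 fell, with medians of -0.62, -1.12 and -0.60 (camera adjusted p = 0.0136, 0.00209 and 0.0372, and 0.122, 0.0574 and 0.174 with an estimated correlation).

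The remaining lists were not called in the wild type response on any day. Of 8 tested PIP5K family genes 1, 1 and 1 rose and 2, 3 and 4 fell (camera adjusted p = 0.999, 0.745 and 0.484). Of 16 other phosphoinositide genes 4, 3 and 6 rose and 3, 6 and 5 fell (camera adjusted p = 0.783, 0.874 and 0.718). Of 14 clock genes 7, 3 and 8 rose and 3, 4 and 1 fell (camera adjusted p = 0.23, 0.896 and 0.0661), and at 5 d the test was upward with a median of -0.07 and a mean of -0.07. Of 5 guard cell markers 0, 1 and 0 rose and 3, 2 and 3 fell (camera adjusted p = 0.175, 0.582 and 0.436). Of 4 root markers 0 rose and 0, 0 and 1 fell (camera adjusted p = 0.895, 0.965 and 0.697). Of 4 flower markers 0, 1 and 2 rose and 1, 0 and 1 fell, with 0 fallen at 2 d adjusted over the list alone (camera adjusted p = 0.717, 0.874 and 0.672). Of 4 genes of the flowering transition 1, 0 and 1 rose and 0, 1 and 0 fell, with 0 risen at 7 d adjusted over the list alone (camera adjusted p = 0.857, 0.353 and 0.768). For root markers and the flowering transition at 2 d, medians of -0.03 and -0.13 were negative and means of 0.21 and 0.08 positive, and for flower markers at 5 d these were -0.39 and 0.42. Of 8 qPCR reference genes 1, 4 and 3 rose and 0, 0 and 1 fell (camera adjusted p = 0.621, 0.207 and 0.643).

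The second comparison asked the same of the mutant. Salicylic acid defence was again the list with the highest median on each day, and the mutant lowered cuticle genes and, at 5 and 7 d, jasmonate genes. Fewer genes passed the threshold than in the wild type, senescence genes rose with smaller medians, and cell cycle genes were not called. In limma 5579 loci were called at 2 d, 2772 higher and 2807 lower, 7278 at 5 d, 3622 higher and 3656 lower, and 7822 at 7 d, 3766 higher and 4056 lower.

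FMO1 rose most at 2 d, from 0.6269 ± 1.09 to 48.45 ± 6.6. The glucanase gene BG3 (AT3G57240) rose from 12.68 ± 5.62 to 418.1 ± 15.3, PCR1 (AT1G14880), of a cadmium resistance protein, from 54.73 ± 8.34 to 1700 ± 103, and ALD1 from 0.9453 ± 0.94 to 38.07 ± 2.56. Most lowered at 2 d and kept under the alternatives were the brassinosteroid signalling gene BRS1 (AT4G30610) (-2.56 ± 0.51), the pectin methylesterase gene PME5 (AT5G47500) (-2.44 ± 0.38) and PDLP3 (AT2G33330), of a plasmodesma protein (-1.85 ± 0.25). At 5 d PR1 rose from 419.3 ± 62 to 44390 ± 7080, and the dioxygenase gene ARD3 (AT2G26400), BG3 and PCR1 followed, with changes of 6.41 ± 0.45, 6.26 ± 0.23 and 6.21 ± 0.11. Most lowered at 5 d were BT2 (AT3G48360), of a nitrate-responsive scaffold protein (-3.74 ± 0.20), the acyltransferase gene GLC (AT1G65450) (-2.68 ± 0.37), the arabinogalactan protein gene AGP21 (AT1G55330) (-2.61 ± 0.35) and NEET (AT5G51720), for an iron-sulfur protein (-2.42 ± 0.18). At 7 d PR1 rose from 826.6 ± 136 to 69750 ± 8380, and UGT72E2 (AT5G66690), which glycosylates lignin precursors, rose from 1.335 ± 0.66 to 181 ± 18.6. ARD3 and PCR1 rose by 7.39 ± 0.45 and 6.57 ± 0.11. Most lowered at 7 d were MRD1 (AT1G53480) (-3.55 ± 0.22), the sugar exporter gene SWEET15 (AT5G13170) (-3.24 ± 0.33) and the iron uptake regulators BHLH100 (AT2G41240) (-3.18 ± 0.24) and bHLH39 (-3.15 ± 0.46).

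All 24 salicylic acid genes rose on each day, with medians of 2.05, 2.75 and 2.58 (camera adjusted p = 1.18e-40, 1.03e-34 and 1.47e-33). Genes of endoplasmic reticulum folding rose in 16, 17 and 17 of 17 cases, with medians of 0.98, 1.36 and 1.17 (camera adjusted p = 6.26e-25, 1.81e-22 and 5.85e-20). Of the pattern recognition genes 11, 11 and 13 of 16 rose (13, 11 and 13 adjusted over the list alone) and 0, 1 and 0 fell (1, 1 and 0 adjusted over the list alone). Their medians were 0.74, 1.03 and 1.16 (camera adjusted p = 8.15e-10, 1.88e-07 and 1.42e-10). Penetration resistance genes rose in 11, 12 and 13 of 17 cases (12, 13 and 13 adjusted over the list alone), with medians of 0.71, 0.76 and 1.07 (camera adjusted p = 1.2e-08, 5.62e-07 and 1.97e-08). Camalexin and indole glucosinolate genes rose in 9, 8 and 10 of 14 cases (9, 9 and 10 adjusted over the list alone), with medians of 0.76, 0.69 and 1.02 (camera adjusted p = 6.64e-07, 3.79e-06 and 6.22e-07). Senescence genes rose in 11, 8 and 8 of 15 cases (12, 8 and 8 adjusted over the list alone), with medians of 0.94, 0.40 and 0.21 (camera adjusted p = 1.2e-08, 0.0177 and 0.00491, that at 5 d 0.0582 with an estimated correlation). SAG12 reached 4.991 ± 1.84 at 5 d and 4.633 ± 1.13 at 7 d in inoculated mutant leaves. Sugar transport genes rose in 4, 4 and 5 of 9 cases, with medians of 0.21, 0.19 and 0.28 (camera adjusted p = 0.000218, 0.0106 and 0.0179, the last 2 values 0.0559 and 0.0776 with an estimated correlation). Of 8 genes of ethylene and jasmonate defence 5, 3 and 4 rose (6, 3 and 4 adjusted over the list alone), with medians of 1.69, -0.01 and 0.87. The list was called at 2 d (camera adjusted p = 1.8e-05) and at 7 d (camera adjusted p = 0.0452, and 0.292 with an estimated correlation).

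Photosynthesis genes fell in 38, 39 and 39 of 39 cases, with medians of -0.47, -0.65 and -0.66 (camera adjusted p = 3.85e-17, 1.55e-18 and 4.26e-16, and 0.169, 0.146 and 0.188 with an estimated correlation). Epidermis and cuticle markers fell in 7, 8 and 10 of 11 cases (8, 10 and 11 adjusted over the list alone), with medians of -0.61, -0.84 and -0.95 (camera adjusted p = 0.000375, 6.6e-06 and 1.14e-06). Jasmonate genes fell in 1, 15 and 17 of 18 cases (1, 17 and 17 adjusted over the list alone), with medians of 0.15, -0.62 and -0.82 (camera adjusted p = 0.374, 2.55e-08 and 2.03e-11). VSP1 fell from 22330 ± 1880 to 8258 ± 675 at 5 d and from 28970 ± 2220 to 5007 ± 414 at 7 d. Abscisic acid and cold genes fell in 1, 13 and 19 of 21 cases (2, 14 and 20 adjusted over the list alone), with medians of 0.16, -0.48 and -1.01 (camera adjusted p = 0.176, 2.24e-05 and 2.67e-11). Phenylpropanoid genes fell in 9, 8 and 12 of 16 cases, with medians of -0.33, -0.44 and -1.14 (camera adjusted p = 0.00106, 0.0564 and 2.14e-05). Auxin genes fell in 6, 10 and 11 of 18 cases, with medians of -0.28, -0.56 and -0.51 (camera adjusted p = 0.0636, 0.014 and 0.0175), while the auxin-conjugating gene GH3.3 rose by 2.55 at 5 d and 3.07 at 7 d. Aliphatic glucosinolate genes fell in 6, 9 and 3 of 13 cases, with medians of -0.24, -0.43 and 0.07 (camera adjusted p = 0.0336, 0.00415 and 0.977, the first 0.0551 with an estimated correlation). Cell cycle genes fell in 1, 1 and 0 of 11 cases (0 on each day adjusted over the list alone), and the list was not called (camera adjusted p = 0.192, 0.966 and 0.991). The PIP5K family, other phosphoinositide genes, the clock, the reference genes and the markers of roots, flowers, the flowering transition, guard cells and phloem were not called on any day. Among genes of the flowering transition 2 of 4 fell at 7 d (4 adjusted over the list alone), and 2 of 16 other phosphoinositide genes rose at 2 d (1 adjusted over the list alone). The median and the test differed in sign for other phosphoinositide genes at 2 d, ethylene and jasmonate defence and root markers at 5 d and guard cell markers at 7 d. The mean and the test did so for root markers and the flowering transition at 2 d, the PIP5K family at 5 and 7 d, and root markers, cell cycle and clock genes at 7 d.

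Set side by side, the responses of the lines mostly ran in the same direction and differed in size. Across loci, which are not independent replicates, the log2 responses correlated with r = 0.761 at 2 d, 0.753 at 5 d and 0.714 at 7 d. Loci called in both lines numbered 4488, 6128 and 6310, and 97.8%, 96.2% and 92.5% of them changed in the same direction. Over loci chosen on the wild type response of another day, the median ratio of mutant to wild type response was 0.55, 0.45 and 0.43, and the response was smaller in the mutant for 79.7%, 85.4% and 86.9%. Over loci chosen on the mutant response of another day the ratios were 0.64, 0.64 and 0.61.

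The third comparison asked how the mutant differs before infection. On all 3 days mock leaves of the mutant had raised phenylpropanoid and anthocyanin genes, lowered aliphatic glucosinolate genes and lower PDF1.2A, PDF1.2B and PDF1.2C. Jasmonate genes were raised at 2 and 7 d. In limma 9796 loci were called at 2 d, 4760 higher and 5036 lower, 11499 at 5 d, 5637 higher and 5862 lower, and 11607 at 7 d, 5799 higher and 5808 lower. Averaged over days 13644 were called, 6689 higher and 6955 lower.

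THI2.1 (AT1G72260), a thionin gene induced by jasmonate, was among the most raised at 2 and 5 d, at 123.9 ± 24.2 and 497 ± 57.4 in the mutant against 0.3676 ± 0.637 and 6.849 ± 2.27 in the wild type. The ratio at 2 d was 350 (95% interval 62.4 to 13800). Others at 2 d were CYP81F4 (AT4G37410), an indole glucosinolate gene (6.50 ± 0.35), VSP1, at 13990 ± 1140 against 245.8 ± 6.12, and the terpene synthase gene TPS02 (AT4G16730) (145-fold, 95% interval 25.7 to 5780). At 5 d they were PYK10 (AT3G09260), a beta-glucosidase gene best known from roots (205.1 ± 53.5 against 1.785 ± 1.2), the lectin gene JAL33 (AT3G16450) (126-fold, 95% interval 22.2 to 5020) and GPT2 (AT1G61800), of a plastid sugar phosphate transporter (584.2 ± 47.6 against 14.03 ± 2.08). At 7 d they were the nitrilase gene NIT2 (AT3G44300) (1761 ± 201 against 15.7 ± 5.26), RTFL21 (AT1G67265), of a small peptide family (6.62 ± 0.43), the carotenoid cleavage gene CCD8 (AT4G32810) (184-fold, 95% interval 32.7 to 7310) and the thioredoxin gene TH7 (AT1G59730) (at least 40.2-fold). Most lowered at 2 d were PDF1.2A, PDF1.2C, PDF1.2B and SEP1 (AT5G15800), a floral regulator, with PDF1.2A 339-fold lower (95% interval 115 to 1640) and SEP1 102-fold lower (95% interval 27.9 to 850). At 5 d AACT1 (AT5G61160), which makes coumaroylagmatine, an antifungal amide, was lowest relative to the wild type (-4.88 ± 0.37), with the laccase gene LAC11 (AT5G03260) (-4.74 ± 0.57), BPS3 (AT4G01360) (-4.57 ± 0.34) and MRD1 (-4.49 ± 0.22). At 7 d AACT1 was 254-fold lower (95% interval 86.4 to 1230), and PDF1.2A, PDF1.3 and PDF1.2C were lower by -7.01 ± 0.25, -6.95 ± 0.58 and -6.52 ± 0.34. Averaged over days THI2.1, RTFL21, NIT2 and GPT2 were most raised (5.79, 5.52, 5.20 and 5.11), and PDF1.2A, AACT1, PDF1.3 and PDF1.2B most lowered (-5.66, -5.46, -5.21 and -5.07).

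Jasmonate genes were higher in 17, 10 and 14 of 18 cases and lower in 0, 7 and 1, with medians of 1.98, 0.55 and 0.67 (camera adjusted p = 1.7e-21, 0.0398 and 1.7e-05, that at 5 d 0.244 with an estimated correlation). All 13 aliphatic glucosinolate genes were lower on each day, with medians of -1.80, -1.93 and -2.68 (camera adjusted p = 1.3e-13, 5.85e-12 and 1.7e-14). CYP79F1 (AT1G16410), the first enzyme of this pathway, measured 998.3 ± 58.4, 498.2 ± 56.7 and 276.5 ± 3.53 in the mutant against 3672 ± 66.3, 4178 ± 260 and 3468 ± 41. Phenylpropanoid and anthocyanin genes were higher in 12, 13 and 13 of 16 cases, with medians of 0.84, 1.40 and 1.01 (camera adjusted p = 1.28e-05, 2.88e-06 and 0.000251). Salicylic acid genes were lower in 12, 14 and 9 of 24 cases (15, 14 and 9 adjusted over the list alone) and higher in 4, 7 and 12. Medians were -0.54, -0.63 and 0.34 (camera adjusted p = 0.00189, 0.0609 and 0.504). Of the 8 ethylene and jasmonate defence genes 4, 4 and 5 were lower, with medians of -2.18, -1.33 and -3.57 (camera adjusted p = 0.179, 0.238 and 0.0163, the last 0.223 with an estimated correlation). Abscisic acid and cold genes were lower in 12 of 21 cases at 5 d, with a median of -0.50, and higher in 16 at 7 d, with a median of 0.85. Both calls were lost with an estimated correlation (camera adjusted p = 0.0277 and 0.000175, against 0.219 and 0.0675 with an estimated correlation).

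Guard cell markers were lower in 3, 4 and 5 of 5 cases, with medians of -1.38, -2.07 and -1.57 (camera adjusted p = 0.0795, 0.0353 and 0.0197, the last 2 values 0.142 and 0.144 with an estimated correlation). Phloem markers were lower in 4, 5 and 4 of 5 cases, with medians of -0.73, -1.33 and -1.55 (camera adjusted p = 0.0379, 0.0038 and 0.0163, and 0.246, 0.0788 and 0.158 with an estimated correlation). Photosynthesis genes went both ways at 2 and 5 d, with 15 and 13 of 39 higher and 13 and 15 lower (16 and 13 higher, 14 and 15 lower adjusted over the list alone), and 25 were lower at 7 d (26 adjusted over the list alone). The median at 7 d was -0.47 (camera adjusted p = 3.2e-06, and 0.577 with an estimated correlation). Medians at 2 and 5 d of 0.10 and 0.02 were positive while the means of -0.08 and -0.15 and the tests were negative. At 5 d early defence, penetration resistance and sugar transport genes were lower in 9 of 16, 10 of 17 and 6 of 9 cases, and folding genes higher in 12 of 17. These calls were lost with an estimated correlation (camera adjusted p = 0.0108, 0.0277, 0.0108 and 0.0277, against 0.0788, 0.0788, 0.0788 and 0.0828 with an estimated correlation). Senescence genes were higher in 9 of 15 cases at 7 d (10 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 0.0235, and 0.142 with an estimated correlation). The PIP5K family (2 of 8 genes mutated) was called lower on each day, with medians of -0.98, -0.82 and -0.86 (camera adjusted p = 0.023, 0.0398 and 0.0201, and 0.246, 0.24 and 0.223 with an estimated correlation). Averaged over days auxin genes were lower in 14 of 18 cases, with a median of -0.38 (camera adjusted p = 0.0323, and 0.116 with an estimated correlation).

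Other lists were not called on single days in mock leaves. Among them the camalexin list had 7, 6 and 7 of 14 genes higher and 6 lower on each day, with 8 higher at 7 d adjusted over the list alone. Its median at 7 d was 0.65, or 0.47 with members at 0 reads set to their bound, while the test was downward (camera adjusted p = 0.913). Other phosphoinositide genes were lower in 6, 7 and 10 of 16 cases (camera adjusted p = 0.217, 0.0525 and 0.129). Cuticle markers were lower in 4, 2 and 5 of 11 cases (5, 2 and 5 adjusted over the list alone) and cell cycle genes in 0, 2 and 2 of 11 cases (0, 2 and 1 adjusted over the list alone). Clock genes were lower in 7, 6 and 7 of 14 cases. Of the flowering genes FT (AT1G65480), which promotes flowering, measured 0.9195 ± 0.909, 1.32 ± 1.5 and 1.971 ± 0.116 in the mutant against 26.21 ± 9.02, 45.43 ± 17.4 and 24 ± 3.81. FLC (AT5G10140), which represses flowering, measured 127.5 ± 10.2, 100.7 ± 13.5 and 108.4 ± 6.58 against 22.8 ± 7, 17.92 ± 2.35 and 6.244 ± 3.32. Of the 8 reference genes 3, 4 and 4 were higher and 0, 1 and 2 lower (camera adjusted p = 0.276, 0.106 and 0.304), with UBC21 higher by 0.47, 0.77 and 0.92. The median or the mean differed in sign from the test for early defence, penetration resistance and senescence genes at 2 d. They also did for camalexin, cell cycle and root genes at 5 d, and for penetration resistance, root, flower and flowering transition genes at 7 d.

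The fourth comparison asked how the lines differ once infected. Inoculated mutant leaves had higher jasmonate and anthocyanin genes, lower aliphatic glucosinolate genes and lower salicylic acid defence than inoculated wild type leaves. At 5 and 7 d they also had lower senescence genes and higher cuticle genes, while PR1 was higher in the mutant at 5 and 7 d. In limma 11272 loci were called at 2 d, 5570 higher and 5702 lower, 11824 at 5 d, 5948 higher and 5876 lower, and 11532 at 7 d, 5819 higher and 5713 lower. Averaged over days 14257 were called, 7135 higher and 7122 lower.

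Most raised at 2 d were ATCSLA15 (AT4G13410), of a mannan synthase (378.2 ± 13.8 against 1.752 ± 1.59), CYP81F4 (307-fold, 95% interval 84.7 to 2540), THI2.1 (6.71 ± 0.37) and IGMT5 (AT1G76790), an indole glucosinolate methyltransferase (402.7 ± 25.6 against 3.422 ± 1.81). At 5 d they were THI2.1 (736-fold, 95% interval 132 to 29100), NUDT24 (542.5 ± 20.9 against 2.717 ± 2.57), ATCSLA15 and VSP1 (8258 ± 675 against 67.95 ± 20.2). At 7 d they were NUDT24 (at least 349-fold), CYP81F4 (at least 152-fold), IGMT5 (334.8 ± 37.8 against 1.973 ± 0.902) and MLP423 (AT1G24020), a latex protein gene (252-fold, 95% interval 69.4 to 2080). Most lowered at 2 d were HR3 (AT3G50470), a homolog of a gene for broad mildew resistance, SEP1 (-5.05 ± 0.53), the calmodulin-like gene CML41 (AT3G50770) (43.18 ± 4 against 790.1 ± 48.2) and the receptor-like gene RLP20 (AT2G25440) (19.67 ± 4.95 against 350.9 ± 24.1). HR3 had 0 reads in all 18 mutant libraries and was at least 69.2-fold, 119-fold and 112-fold lower at 2, 5 and 7 d. At 5 d SAG12 (4.991 ± 1.84 against 3099 ± 155), the polygalacturonase gene PGAZAT (AT2G41850) (3.223 ± 1.62 against 199.7 ± 34.1) and the galactosidase gene BGAL4 (AT5G56870) (45.83 ± 1.45 against 1469 ± 157) were most lowered with HR3. At 7 d SAG12, BGAL4 (47.77 ± 5.22 against 1219 ± 190) and the polygalacturonase gene ADPG1 (AT3G57510) (-4.93 ± 0.51) were most lowered with HR3. Averaged over days NUDT24, CYP81F4, THI2.1 and ATCSLA15 were most raised (7.46, 7.03, 6.97 and 6.60), and HR3, SAG12, SEP1 and BGAL4 most lowered (-6.40, -5.91, -4.43 and -4.24).

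Salicylic acid genes were lower in 17, 17 and 16 of 24 cases and higher in 1, 2 and 3, with medians of -0.66, -0.88 and -0.65 (camera adjusted p = 4.81e-06, 9.87e-06 and 0.00268). ICS1 measured 494.3 ± 29.4, 766.5 ± 23.7 and 993.6 ± 47.6 in the mutant against 1849 ± 87.7, 1914 ± 97.3 and 2052 ± 3.38. PR1 measured 5292 ± 330, 44390 ± 7080 and 69750 ± 8380 against 8078 ± 357, 15810 ± 1410 and 15470 ± 2720. Senescence genes were lower in 10, 13 and 9 of 15 cases, with medians of -0.87, -1.90 and -1.09 (camera adjusted p = 0.0159, 5.8e-08 and 0.00179, the first 0.0789 with an estimated correlation). The senescence regulator NAP was lower by -1.67 at 2 d and -2.74 at 5 d. Jasmonate genes were higher in 17, 11 and 12 of 18 cases, with medians of 1.77, 1.39 and 1.147 (camera adjusted p = 2.05e-13, 0.000322 and 0.000605). Phenylpropanoid genes were higher in 13, 11 and 11 of 16 cases, with medians of 1.66, 2.16 and 2.60 (camera adjusted p = 2.95e-06, 0.000204 and 7.65e-05). All 13 aliphatic glucosinolate genes were lower on each day, with medians of -1.47, -1.35 and -1.73 (camera adjusted p = 1.3e-09, 5.39e-09 and 3.16e-11). Cuticle markers were higher in 8, 8 and 9 of 11 cases, with medians of 0.70, 1.06 and 1.06 (camera adjusted p = 0.00482, 3.39e-05 and 7.65e-05, the first 0.1 with an estimated correlation). LTP1 measured 6061 ± 142, 4197 ± 1150 and 3490 ± 769 against 961.5 ± 67.4, 168.9 ± 15.7 and 200.1 ± 33.7. Folding genes were lower in 16, 8 and 6 of 17 cases (16, 8 and 7 adjusted over the list alone), with medians of -0.73, -0.22 and -0.10 (camera adjusted p = 1.01e-07, 0.0688 and 0.413). BIP3 measured 168.4 ± 14.7 at 2 d in the mutant against 569.1 ± 18.

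Cell cycle genes were higher in 7, 10 and 8 of 11 cases (9, 10 and 8 adjusted over the list alone), with medians of 1.09, 1.72 and 1.60 (camera adjusted p = 0.0857, 0.00899 and 0.0132, the last 0.0631 with an estimated correlation). CYCA2;3 had 0 reads in inoculated wild type leaves at 5 d and was at least 11.3-fold higher in the mutant. Early defence genes were lower in 6, 12 and 10 of 16 cases (5, 12 and 10 adjusted over the list alone), with medians of -0.01, -1.05 and -0.50 (camera adjusted p = 0.333, 0.000955 and 0.0533). Camalexin and indole glucosinolate genes were lower in 6, 10 and 8 of 14 cases (7, 10 and 8 adjusted over the list alone), with medians of -0.11, -0.66 and -0.24 (camera adjusted p = 0.315, 0.000424 and 0.108). PAD3 went the other way at 7 d, at 1289 ± 77.7 against 592.9 ± 36.9. Penetration resistance genes were lower in 8, 9 and 11 of 17 cases (9, 9 and 11 adjusted over the list alone) and called at 5 d, with a median of -0.57 (camera adjusted p = 0.0326). Sugar transport genes were lower in 4, 8 and 6 of 9 cases, with medians of -0.14, -0.84 and -0.95 (camera adjusted p = 0.525, 0.000808 and 0.00359). SWEET15 measured 12.9 ± 4.2 against 295.7 ± 17.6 at 5 d, and CWINV1 398.7 ± 34 against 1042 ± 137. Photosynthesis genes were higher in 23, 28 and 10 of 39 cases, with medians of 0.32, 0.52 and -0.19 (camera adjusted p = 0.0314, 0.000808 and 0.0533, the first 2 values 0.691 and 0.58 with an estimated correlation). Clock genes were lower in 8, 10 and 9 of 14 cases, with medians of -0.27, -0.46 and -0.65 (camera adjusted p = 0.333, 0.0467 and 0.0179, the value at 5 d 0.0517 with an estimated correlation).

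The 8 ethylene and jasmonate defence genes were called higher at 7 d only, with 5 higher and a median of 1.19 (camera adjusted p = 0.0481, and 0.302 with an estimated correlation). The PIP5K family was called lower at 2 d, with 6 of 8 lower (2 of them mutated) and a median of -0.83 (camera adjusted p = 0.00799, and 0.153 with an estimated correlation). Abscisic acid and cold genes went both ways, with 8, 7 and 10 of 21 higher and 8, 10 and 8 lower (camera adjusted p = 0.898, 0.366 and 0.413). Their median at 2 d of -0.04 was negative while the mean of 0.24 and the test were positive. Auxin genes were higher in 6, 7 and 7 of 18 cases (camera adjusted p = 0.356, 0.155 and 0.463), with a median of -0.05 at 7 d against an upward test. Root markers at 2 d had a negative median against an upward test, and at 7 d, like phloem and abscisic acid genes at 5 d, a positive mean against a downward test. Other phosphoinositide genes, reference genes, and the markers of roots, flowers, the flowering transition, guard cells and phloem were not called. FT and FLC stayed apart between the lines after inoculation, with changes of -4.31 and 2.21 at 5 d.

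**Figure D3:**
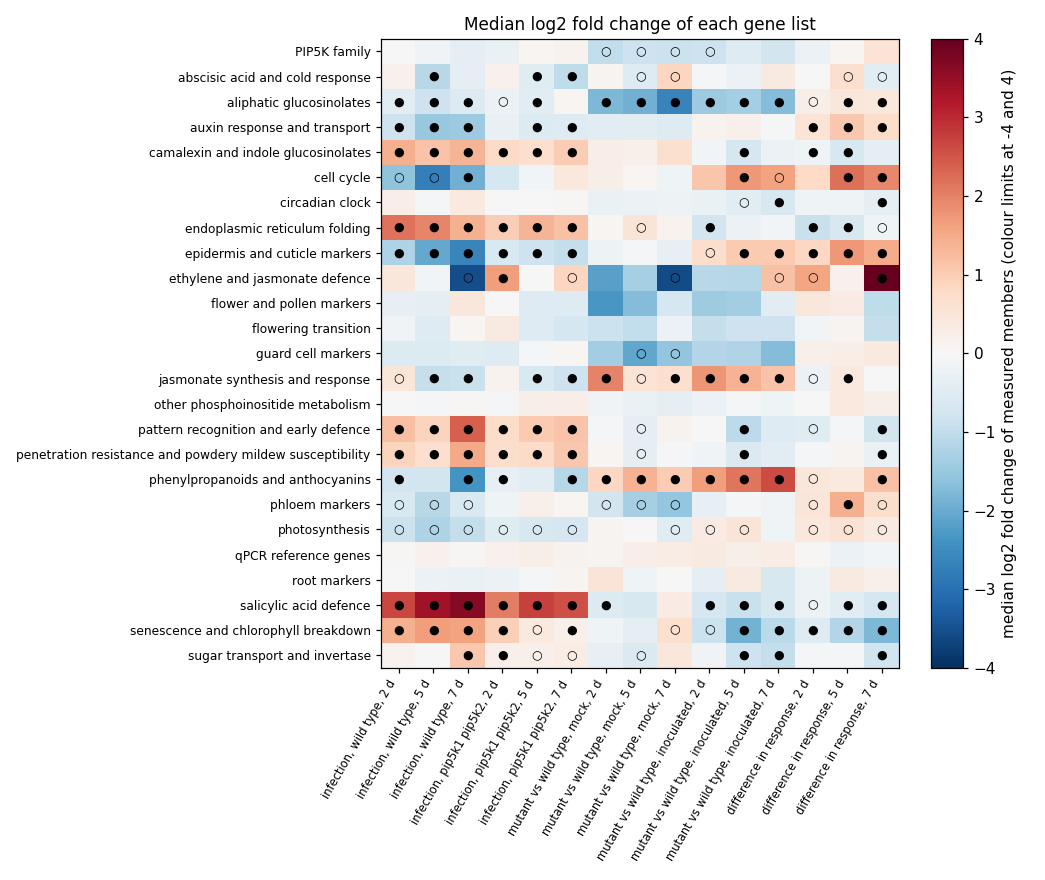
Median log2 change of each gene list in each comparison. Filled dots mark lists called by camera that were kept when the correlation between genes was estimated, open dots those that were lost. Of 216 calls 143 were kept.

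The fifth comparison asked where the response to infection itself differs between the lines. At 5 d senescence, salicylic acid and folding genes rose less in the mutant, and cuticle, cell cycle and auxin genes fell less or did not fall. At 7 d PDF1.2A and PDF1.2C fell in the wild type and did not fall in the mutant, whose mock leaves had fewer of these reads. In limma 2547 loci were called at 2 d, 1381 higher and 1166 lower, 6278 at 5 d, 3417 higher and 2861 lower, and 7066 at 7 d, 3673 higher and 3393 lower. Averaged over days 8558 were called, 4355 higher and 4203 lower. A positive value means that the mutant rose more or fell less than the wild type.

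Among the largest positive differences at 2 d were PDF1.2A (4.68 ± 0.35), PDF1.2C (3.24 ± 0.48), bHLH39 (3.07 ± 0.64) and ATCSLA15 (3.03 ± 0.35), and among the largest negative ones RRTF1 (-3.33 ± 0.44), RLP20 (-3.26 ± 0.58) and GSTU10 (-3.02 ± 0.45). At 5 d PHI-1 (AT1G35140), a phosphate-induced gene (6.25 ± 0.41), GER3 (5.50 ± 0.33), the cell wall gene XTH18 (AT4G30280) (4.91 ± 0.55) and the wax gene CER4 (AT4G33790) (4.77 ± 0.54) differed most upward, and SAG12 (-9.07 ± 0.57), KTI1 (-7.04 ± 0.58), PGAZAT (-6.42 ± 0.74) and DIN2 (-6.20 ± 0.63) most downward. At 7 d PDF1.2C (9.42 ± 0.48), PDF1.2A (8.72 ± 0.35), PDF1.2B (7.83 ± 0.54) and PDF1.3 (7.22 ± 0.82) differed most upward, and KTI1 (-8.36 ± 0.58), DIN2 (-8.20 ± 0.63), the osmotin gene OSM34 (AT4G11650) (-7.25 ± 0.60) and CCD8 (-7.00 ± 0.49) most downward. Inoculated mutant leaves had 139 ± 25.4 of KTI1 at 5 d and 173.4 ± 54.2 at 7 d, against 1552 ± 253 and 1360 ± 283 in the wild type. Mutant mock leaves had 28.16 ± 17.5 and 103.4 ± 25.1, against 1.457 ± 1.27 and 1.966 ± 1.87, so part of the difference in response lay in mock leaves, as for DIN2 and CCD8 at 7 d. Some of these genes had few or 0 reads in a group, so these sizes depend on the pseudocount.

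Senescence genes responded less in the mutant in 9, 14 and 14 of 15 cases (12, 15 and 14 adjusted over the list alone), with medians of -0.53, -1.18 and -1.79 (camera adjusted p = 7.33e-06, 1.27e-11 and 7.52e-14). JUB1 differed by -1.69, -1.91 and -2.36. Folding genes responded less in 14, 12 and 7 of 17 cases (17, 12 and 7 adjusted over the list alone), with medians of -0.91, -0.65 and -0.16 (camera adjusted p = 6.89e-26, 2.19e-07 and 0.0439, the last 0.0923 with an estimated correlation). Salicylic acid genes responded less in 5, 10 and 14 of 24 cases (5, 11 and 14 adjusted over the list alone) and more in 4, 2 and 1 (5, 3 and 2 adjusted over the list alone). Medians were -0.20, -0.43 and -0.67 (camera adjusted p = 0.0494, 0.00156 and 2.43e-05, the first 0.0773 with an estimated correlation). ICS1 differed by -1.73 at 2 d, and the regulator WRKY18 by -1.28, -2.10 and -2.50. Early defence genes responded less in 6, 2 and 7 of 16 cases (6, 2 and 8 adjusted over the list alone), with medians of -0.47, -0.05 and -0.72 (camera adjusted p = 0.0427, 0.869 and 0.00112, the first 0.153 with an estimated correlation). At 5 d the test was upward while the median and the mean of -0.19 were negative. Camalexin and indole glucosinolate genes responded less in 5, 9 and 7 of 14 cases, with medians of -0.17, -0.63 and -0.39 (camera adjusted p = 6.6e-05, 0.000305 and 0.429). The glutathione transferase gene GSTF6 (AT1G02930) differed by -2.32, -2.59 and -2.18, having measured 2019 ± 135 in mutant and 263.2 ± 10.4 in wild type mock leaves at 2 d. Penetration resistance genes were called at 7 d, with 8 of 17 responding less and a median of -0.27 (camera adjusted p = 0.00799), and MLO12 differed by -3.01. Sugar transport genes were called at 7 d, with 7 of 9 responding less and a median of -0.81 (camera adjusted p = 0.00064), and SWEET15 differed by -6.06.

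Cuticle markers differed upward in 8, 9 and 9 of 11 cases (10, 9 and 9 adjusted over the list alone), with medians of 0.84, 1.73 and 1.49 (camera adjusted p = 8.61e-11, 1.65e-09 and 5.51e-09). CER1 differed by 1.24, 3.02 and 3.49. Auxin genes differed upward in 9, 11 and 8 of 18 cases (10, 12 and 8 adjusted over the list alone), with medians of 0.55, 1.09 and 0.72 (camera adjusted p = 7.33e-06, 3.81e-05 and 0.0057). Cell cycle genes differed upward in 0, 7 and 7 of 11 cases (0, 7 and 8 adjusted over the list alone), with medians of 0.80, 2.201 and 1.92 (camera adjusted p = 0.051, 0.00288 and 0.00064). Photosynthesis genes differed upward in 17, 34 and 21 of 39 cases (29, 34 and 24 adjusted over the list alone), with medians of 0.42, 0.57 and 0.37 (camera adjusted p = 8.61e-11, 1.97e-12 and 3.33e-05, and 0.289, 0.282 and 0.505 with an estimated correlation). Phloem markers differed upward in 2, 5 and 3 of 5 cases, with medians of 0.49, 1.44 and 0.72 (camera adjusted p = 0.0412, 3.81e-05 and 0.009, those at 2 and 7 d 0.188 and 0.0923 with an estimated correlation). Aliphatic glucosinolate genes differed upward in 2, 7 and 11 of 13 cases (4, 8 and 11 adjusted over the list alone), with medians of 0.25, 0.45 and 0.44 (camera adjusted p = 0.0416, 0.00168 and 0.000223, the first 0.0773 with an estimated correlation). Phenylpropanoid genes differed upward in 5, 6 and 11 of 16 cases (6, 7 and 11 adjusted over the list alone), with medians of 0.45, 0.38 and 1.19 (camera adjusted p = 0.00883, 0.39 and 0.000244, the first 0.0773 with an estimated correlation). The 8 ethylene and jasmonate defence genes differed upward in 5, 3 and 6 cases, with medians of 1.56, 0.17 and 4.56 (camera adjusted p = 0.00146, 0.973 and 1.08e-05, the first 0.0971 with an estimated correlation).

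Jasmonate genes differed downward in 7 of 18 cases at 2 d (9 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.000797, and 0.0773 with an estimated correlation), and upward in 9 at 5 d, with a median of 0.39 (camera adjusted p = 7.3e-05). At 7 d the list was not called (camera adjusted p = 0.355). Abscisic acid and cold genes differed upward at 5 d, in 11 of 21 cases (12 adjusted over the list alone), and downward at 7 d, in 11 (12 adjusted over the list alone). Both calls were lost with an estimated correlation (camera adjusted p = 0.00781 and 0.00276, against 0.154 and 0.0832 with an estimated correlation). Clock genes were called at 7 d, with 8 of 14 responding less and a median of -0.39 (camera adjusted p = 0.0125). The PIP5K family, other phosphoinositide genes, reference genes, root markers, flower markers, the flowering transition and guard cell markers were not called on any day. PIP5K2 differed by 1.03 ± 0.175 at 7 d (limma, Benjamini-Hochberg adjusted p = 9.2e-06), and PIP5K1 by 0.70 ± 0.19 averaged over days (limma, Benjamini-Hochberg adjusted p = 0.00233). Of all 216 list calls 143 held with the estimated correlation.

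**Figure D4:**
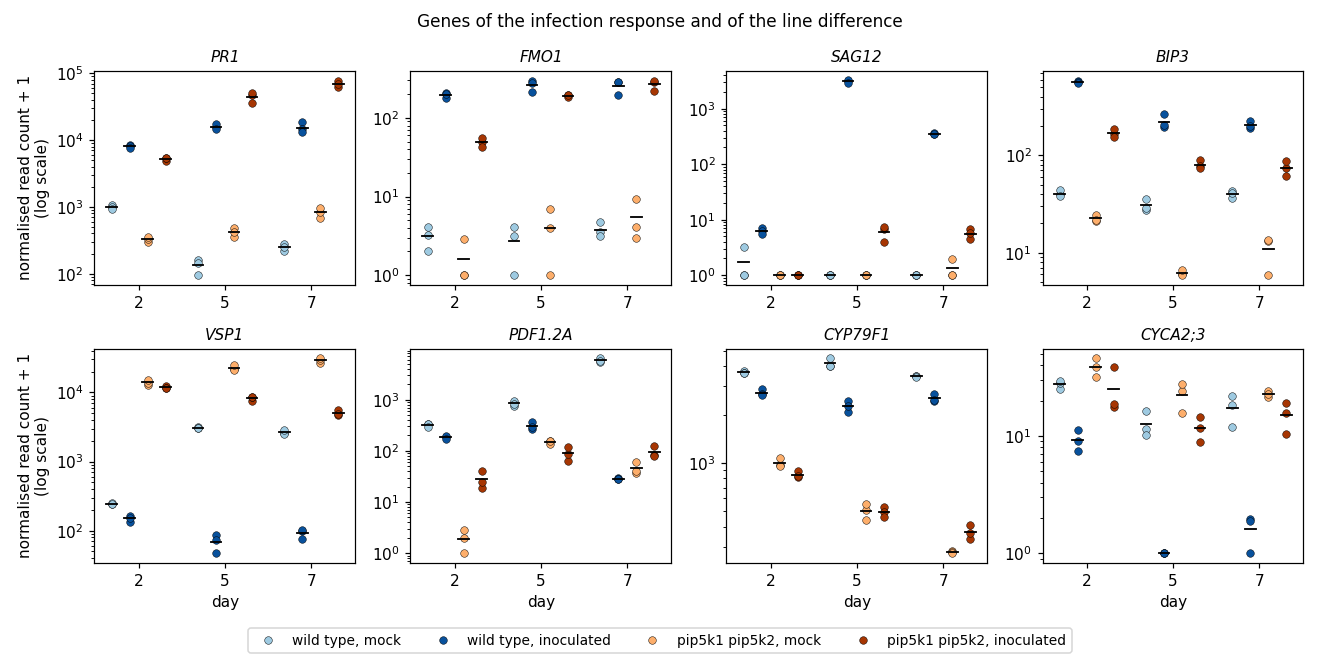
Normalized read counts plus 1, on a log axis, of 8 genes in each library by line, treatment and day, with bars at group means. SAG12 reaches 3099 at 5 d in inoculated wild type leaves and 4.991 in the mutant, and PR1 reaches 15470 and 69750 at 7 d.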

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

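Every result in this part was picked because a test of the difference between lines or days passed, except the mutant jasmonate values given for comparison. The differences in response were planned. All comparisons of days and all counts of splits and rearrangements are tests chosen after the result was seen. Values are differences in log2 response, mutant minus wild type, from limma for genes and as medians of lists called by camera.

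The difference in response was called for 2547 loci at 2 d, 6278 at 5 d, 7066 at 7 d and 8558 averaged over days. Of 100 splits of the libraries 16 called as many at 2 d, 12 at 5 d and 7 at 7 d, the real split included, with 9616, 9791 and 9870 loci in the highest of the others. These splits do not exclude chance on single days. Of the others calling as many, 12, 10 and 6 exchange line mostly in 1 treatment, which turns line differences into response differences. Averaged over days 2 of 100 splits called as many, the other (8613) of that kind, so they cannot decide. When what the additive effects of line and treatment leave over was rearranged, 1 of 100 arrangements called as many in each case, the real one, with 699, 2868, 4099 and 1701 loci in the highest other at 2, 5 and 7 d and averaged, so chance arrangement is excluded by this second test.

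For the 12 comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05; in each 1 split, the real one, called as many. The real counts for the wild type response were 9030, 11668 and 11657, with 1, 1 and 0 in the highest other split, and for the mutant response 5579, 7278 and 7822, with 0, 3 and 727. For the lines in mock leaves they were 9796, 11499 and 11607, with 1, 4 and 2, and in inoculated leaves 11272, 11824 and 11532, with 0, 0 and 1. Averaged over days, 1 of 100 splits, the real one, called as many as 13644 in mock and 14257 in inoculated leaves, with 10976 and 8832 in the highest other, and chance is excluded.

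At 2 d the list medians were -0.195 for salicylic acid defence, -0.234 for jasmonate genes, 1.564 for ethylene and jasmonate defence, -0.471 for early defence, -0.165 for camalexin, 0.248 for aliphatic glucosinolates, 0.422 for photosynthesis and -0.525 for senescence. They were -0.905 for folding in the endoplasmic reticulum, 0.545 for auxin, 0.445 for phenylpropanoids, 0.488 for phloem and 0.842 for cuticle. Of these, calls were lost with an estimated correlation for salicylic acid defence, jasmonate, aliphatic glucosinolates and phenylpropanoids (adjusted p = 0.0773 each), ethylene and jasmonate defence (0.0971), early defence (0.153), phloem (0.188) and photosynthesis (0.289). At 5 d they were -0.426 for salicylic acid defence, 0.389 for jasmonate, -0.63 for camalexin, 0.452 for aliphatic glucosinolates, 0.572 for photosynthesis and -1.175 for senescence. They were -0.645 for folding, 0.632 for abscisic acid and cold, 1.087 for auxin, 2.201 for cell cycle, 1.444 for phloem and 1.726 for cuticle; with an estimated correlation the calls of photosynthesis (adjusted p = 0.282) and abscisic acid (0.154) were lost.

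At 7 d the list medians were -0.666 for salicylic acid defence, 4.561 for ethylene and jasmonate defence, -0.719 for early defence, 0.435 for aliphatic glucosinolates, -0.271 for penetration resistance, -0.807 for sugar transport, 0.373 for photosynthesis and -1.787 for senescence. They were -0.159 for folding, -0.429 for abscisic acid and cold, 0.724 for auxin, 1.917 for cell cycle, 1.186 for phenylpropanoids, -0.394 for the clock, 0.716 for phloem and 1.488 for cuticle. Lost with an estimated correlation were photosynthesis (adjusted p = 0.505), abscisic acid (0.0832), and folding and phloem (0.0923 each). Averaged over days they were -0.544 for salicylic acid defence, 2.286 for ethylene and jasmonate defence, -0.515 for early defence, -0.537 for camalexin, 0.323 for aliphatic glucosinolates, 0.449 for photosynthesis and -1.048 for senescence. They were -0.578 for folding, 0.64 for auxin, 1.757 for cell cycle, 0.756 for phenylpropanoids, -0.168 for the clock, 0.802 for phloem and 1.348 for cuticle. Lost there were photosynthesis (adjusted p = 0.234), camalexin (0.132), early defence (0.116), ethylene and jasmonate defence (0.107), and phenylpropanoids and the clock (0.0566 each).

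Among genes at 2 d the differences were 4.68 for PDF1.2A, 3.24 for PDF1.2C, 3.07 for bHLH39, 3.03 for ATCSLA15, -3.34 for CCR4, -3.33 for RRTF1, -3.26 for RLP20 and -3.02 for GSTU10; the call of CCR4 ended with a pseudocount of 0.1 (adjusted p = 0.0842). At 5 d they were 6.25 for PHI-1, 5.5 for GER3, 4.91 for XTH18, 4.77 for CER4, -9.07 for SAG12, -7.04 for KTI1, -6.42 for PGAZAT and -6.2 for DIN2. At 7 d they were 9.42 for PDF1.2C, 8.72 for PDF1.2A, 7.83 for PDF1.2B, 7.22 for PDF1.3, -8.36 for KTI1, -8.2 for DIN2, -7.25 for OSM34 and -7 for CCD8. Averaged over days they were 4.78 for PDF1.2C, 4.69 for PDF1.2A, 4.31 for PDF1.3, 3.98 for GER3, -5.83 for SAG12, -5.56 for KTI1, -4.43 for DOX1 and -4.32 for DIN2. Fitted values of genes with few or 0 reads in a group depend on the pseudocount and are no bound.

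Lists called in opposite directions on different days within 1 comparison were compared by camera, Benjamini-Hochberg adjusted, including the differences in response. Of the opposite calls these were lost with an estimated correlation: wild type jasmonate at 2 d (adjusted p = 0.153), abscisic acid in mock leaves at 5 and 7 d (0.219 and 0.0675), and in the difference in response jasmonate at 2 d (0.0773) and abscisic acid at 5 and 7 d (0.154 and 0.0832). In the wild type the jasmonate response was lower at 5 d than at 2 d by a median of -1.522 (adjusted p = 6.26e-22, and 1.86e-05 with an estimated correlation) and lower at 7 d than at 2 d by -1.338 (adjusted p = 1e-23, and 4.89e-06 with an estimated correlation). The line difference of abscisic acid and cold genes in mock leaves was higher at 7 d than at 5 d by 1.274 (adjusted p = 4.14e-18, and 4.65e-05 with an estimated correlation). The difference in response of jasmonate genes was higher at 5 d than at 2 d by 0.788 (adjusted p = 6.21e-11, and 0.0023 with an estimated correlation), and that of abscisic acid and cold genes was lower at 7 d than at 5 d by -1.06 (adjusted p = 3.58e-13, and 0.000854 with an estimated correlation).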

How the results depend on the processing

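The tests with edgeR and TMM factors were chosen after the result was seen; the other settings were planned. No setting reversed a named gene: 0 of 1697 pairs of gene and comparison changed direction, and calls ended for 7 with the replicate block, 27 with TMM, 28 with median-of-ratios factors, 29 without a filter, 37 with DESeq2, 40 with only the libraries of the groups compared and 65 with a pseudocount of 0.1. CCR4 at 2 d was -3.604 with a pseudocount of 0.1 (adjusted p = 0.0842). TMM moved the median of all loci by at most 0.031. The cause of these changes was not tested.

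With an absolute log2 change of at least 1, the wild type response held 3258, 5325 and 5643 loci at 2, 5 and 7 d and the mutant response 1316, 2101 and 2216. The lines differed at 3030, 4568 and 4517 loci in mock leaves (3626 averaged) and 4258, 4917 and 4646 in inoculated leaves (4536 averaged), and the difference in response held 765, 2573 and 3140 (2292 averaged). The share higher then moved from 49.7% to 62.5% and from 49.8% to 62.2% for the mutant response at 2 and 5 d, from 50.4% to 40.3% for the wild type at 5 d, and from 54.4% to 68.2% and 50.9% to 67% for the difference in response at 5 d and averaged. With only the compared libraries the difference in response at 2 d was called for 3958 loci. No other setting run moved any of the 18 counts by more than 1.5 times.

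The replicate numbers do not pair the samples: 2 of 36 correlations of same-numbered libraries exceeded 0.1, in a range of -0.2 to 0.24. With the replicate block the counts were 8951, 11601 and 11623 for the wild type response, 5515, 7228 and 7747 for the mutant, 9730, 11457 and 11553 in mock leaves (13611 averaged), 11224, 11798 and 11495 in inoculated leaves (14229 averaged) and 2480, 6215 and 6990 for the difference in response (8491 averaged). The replicate block kept 215 of 216 list calls and ended that of salicylic acid defence at 2 d in the difference in response (camera adjusted p = 0.0504).

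Leaving out each library in turn gave 8083 to 8246, 10952 to 11109 and 10965 to 11262 loci for the wild type, 4575 to 5088, 6461 to 6841 and 6810 to 7627 for the mutant, 8606 to 9154, 10643 to 10938 and 10673 to 11411 in mock leaves (13401 to 13642 averaged), 10421 to 10594, 10959 to 11367 and 10626 to 11188 in inoculated leaves (14020 to 14221 averaged), and 1955 to 2534, 5652 to 6018 and 6431 to 7031 for the difference in response (8287 to 8627 averaged). It ended 503 of 16884 calls of named genes.

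Leaving out a library ended 43 of 2190 list calls by camera, in 14 different tests whose calls were also lost with an estimated correlation, and reversed 0. In the difference in response these were salicylic acid defence (adjusted p up to 0.0946), early defence (0.0841), aliphatic glucosinolates (0.0668) and phloem (0.102) at 2 d, folding at 7 d (0.0656) and the clock averaged (0.0523). The others were phloem in the wild type (0.0538) and ethylene and jasmonate defence in the mutant (0.133) at 7 d, and in mock leaves phloem at 2 d (0.0623) and photosynthesis averaged (0.0791). In inoculated leaves they were photosynthesis at 2 d (0.086), the clock at 5 d (0.0572), ethylene and jasmonate defence at 7 d (0.0908) and the PIP5K family averaged (0.051). The libraries were, in the wild type, replicates 2 and 3 of inoculated leaves on each day, 1 and 2 of mock leaves at 2 d and 2 at 7 d. In the mutant they were all 3 of inoculated leaves at 2 d, 2 and 3 at 5 d and 1 and 2 at 7 d, and of mock leaves 1 and 3 at 2 d and 1 and 2 at 7 d.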

Other observations

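The tests of a wider sulfur deficiency response and of the share of reads in the most abundant loci in mock leaves were written before their results were seen, and the other tests in this part were chosen after the result was seen. Genes of sulfur deficiency were chosen after values were seen. In mutant mock leaves, averaged over days, LSU1 (AT3G49580) was higher by 3.78 ± 0.09, LSU3 (AT3G49570) by 3.31 ± 0.09 and SDI1 (AT5G48850) by 3.16 ± 0.09; these genes are induced when sulfur is short, and SDI1 represses aliphatic glucosinolate synthesis. Of 12 further sulfur deficiency genes 10 were measured, with 8 higher and 1 lower. They include the sulfate transporter SULTR1;2 (AT1G78000), higher by 3.652, and AT5G26220, which degrades glutathione, higher by 2.935, while SULTR2;1 (AT5G10180) was lower by -1.267.

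Raised LSU1, LSU3 and SDI1 went with lowered aliphatic glucosinolate genes, with a median of -2.24 over 13 genes. Scaling of the libraries moves all loci alike and is argued against, since the median of the further sulfur genes lay 3.39 log2 (standard error 0.61 over genes) above that of the glucosinolate genes; earlier tests by TMM factors, which moved too little, and by LSU1, LSU3 and SDI1 themselves were replaced. A wider sulfur deficiency response may account for it, since the further genes had a median of 1.15 (camera p = 0.000368, and 0.00107 with an estimated correlation), although the loci with at least 4-fold differences had been listed before that test was written. Whether growth conditions or the mutated genes account for that response was not tested.

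The infection response was smaller in the mutant. Larger spread in mutant groups does not shrink a median response. Median response ratios of 0.55, 0.45 and 0.43 at 2, 5 and 7 d argue against it. Mutant spread ratios were 1.05, 1.35 and, over the bound, 1.53 mock and 0.93, 0.94 and 0.9 inoculated (median 1). The spread test replaced one by the response. Scaling of the libraries is argued against by median response ratios at 7 d of 0.54 over raised and 0.37 over lowered loci, since a factor per library cannot shrink both; the test by TMM factors was replaced here too. A wild type response already in mock mutant leaves is argued against at 2 and 5 d (0.01 and -0.13 of the shortfall). At 7 d such a response may account for part, since mutant mock leaves lay along the 5 d wild type response by 0.46 of the shortfall at 5 d and 0.49 of that at 7 d. A difference in fungal growth or in signalling between the lines stays open and was not tested.

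Another pattern is the 149 loci that differed at least 4-fold between the lines in both treatments on every day, 92 higher and 57 lower in the mutant. Exchanged line labels are argued against by 0 libraries with PIP5K1 on the side of the other line, and few loci taking a larger share of reads in mock leaves by a mean difference of 1.2 percentage points in the 100 most abundant loci (2.5, 2.4 and -1.3 at 2, 5 and 7 d). In inoculated leaves the differences of 6.1, 7.2 and 2.5 moved all other loci by at most 0.17 log2 between any mutant and wild type library of a day, which argues against it there; this test replaced one by the mean difference, which did not decide. Chromosome segments beside PIP5K1 and PIP5K2 are argued against for the 104 loci on other chromosomes; within 100 tested loci of either gene there were 4, AT1G76530, AT1G76780, IGMT5 and NIA1, against a median of 3 in random sets and 6 at their 95% point, which leaves such segments open for those. Segments of another genotype elsewhere in the genome cannot be told apart from other causes, since HR3 was the 1 locus silent in 1 line only, with a share of 0 near another, and an effect of the mutated genes stays open and was not tested.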
